A study of Mus musculus with 12 samples.

How the data were processed

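Gene expression was measured by RNA sequencing of total RNA from astrocytes of the cerebral cortex, isolated by FACS from wild-type C57BL/6J mice. There were 12 libraries in 6 groups of 2 (sham and days 1, 3, 7, 21 and 60 after stroke). Whether a library came from 1 animal or from a pool is not stated. The marker of the sort is not stated either.

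The deposited files hold raw counts per gene symbol, 1 file per library and 1 table of the whole series. The authors' processing notes name Bowtie2 2.3.4.2, HTSeq 0.6.1 and the mm10 build. The annotation, the strand setting, the handling of reads that match several genes and any filter on genes are not stated. Each file holds 15774 genes, of which 2 have 0 counts in all libraries. Of these symbols 15110 are GENCODE gene names and 14901 are RefSeq names, 14872 of them protein-coding. The table of the whole series was checked against the sample files and was identical in 189288 of 189288 values.

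Replicate 1 of each group holds 13006008 to 16575045 counts over 14616 to 15443 detected genes. Replicate 2 holds 97056596 to 156128922 counts over 15081 to 15517 detected genes. In each group replicate 2 is 6.30 to 9.63 times as deep as replicate 1. A level of 3 counts in each library, used as the floor for genes with 0 counts, corresponds to a mean of 0.0968 to 0.115 CPM. Where a group held 1 to 3 counts in all, CPM values are given in place of a fold, except in the section of flagged results, which also prints fitted values. CPM values divide each count by the library total scaled with TMM factors (0.689 to 1.22). The percent of counts in a list uses the plain totals.

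Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the group design and a minimum count of 10, which left 15635. All 12 libraries entered 1 quasi-likelihood fit with a coefficient for each group (6 residual degrees of freedom, 4.15 prior degrees of freedom, and a median biological coefficient of variation of 0.408). Each of the 5 times was compared with sham and with the time before it. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 within its comparison, from the edgeR quasi-likelihood F test. Every adjusted p of a gene printed here comes from that test unless another tool is named. The standard error of a log2 fold change is its size divided by the square root of F. All groups were also tested together with 5 contrasts, and pairs of times were contrasted to find genes higher than sham at one time and lower at another. Log2 CPM for principal components, correlations and the time of highest mean used a prior count of 2.

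Because the 5 comparisons share the sham libraries, 20 data sets with no change were simulated to find the correlation that the shared libraries give on their own. The numbers of the replicates are not said to mark a batch. The difference between replicate 2 and replicate 1 of each gene correlated between groups at 0.319 to 0.713 in 15 of 15 pairs of groups, above a threshold of 0.1. A fit with the replicate number as a block (5 residual degrees of freedom) was therefore run as an alternative, and its values are given beside counts that it moved by over 1.5 times.

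Gene lists numbered 35, of which 26 cover astrocyte and injury processes and 9 hold markers of other cell types that a sort could carry along. Of 646 list entries 14 are not in the files, among them the hemoglobin genes, Meg3, Ly6g, C1s, C1s1, H2-Q6, H2-Q7, Msmo1 and Ugt1a1, and Ifit3b was matched to I830012O16Rik. Lists were tested with camera in limma 3.58.1, with the preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. An estimated correlation and fry were alternatives. Beside each test stand the members that rose, fell or did not pass over all genes, and those that passed with p adjusted within the list. Members at 0 counts in a group enter a list's median at their bound.

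Single genes were named by a rule. For each comparison with sham it takes the 8 largest positive and 8 largest negative log2 fold changes, and for each comparison of neighbouring times the 5 and 5 largest. These genes had to have an adjusted p under 0.05, at least 10 CPM in the higher group, both libraries of one group above both of the other, and a symbol other than a Gm, Rik, LOC or clone name. Where none passed, the 3 genes with the smallest unadjusted p in each direction were named and said not to pass. In each list up to 4 members were named, those called with the largest absolute change, or the most abundant where fewer than 2 were called. The rule takes the 25 landmark genes in every comparison, whatever their result. Of these, Cxcl10, Top2a, Slc1a3, Aldh1l1, Glul, Kcnj10, Clu and Hmgcs1 are not described below. Of 413 genes named by the rule, 411 are in the GENCODE annotation of mm10 and 0 of these are non-coding. Exons of 8 overlap a coding gene on the same strand and exons of 47 one on the opposite strand, so reads of these genes can be shared if the strand was not used.

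The groups, comparisons, tests, lists, landmark genes, naming rule and most alternatives were fixed before the data were examined. Alternatives were DESeq2 size factors and upper-quartile factors, no filter, a stricter filter (a mean of 10 CPM and at least 1 CPM in 4 libraries), DESeq2 1.42.0, limma-voom, the replicate block in edgeR and DESeq2, fits of the 4 libraries compared, a log2 fold change of at least 1, the table of the whole series and each library left out in turn. Further alternatives were added later and are named as such in the closing section. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

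The fit was tested on simulated data with the depths of these libraries. With 200 changed genes, 0 of 50 genes changed 2-fold, 6 of 50 changed 4-fold, 30 of 50 changed 16-fold and 42 of 50 changed 64-fold were called at day 1, with 3 false calls among 81. With 4000 changed genes the calls were 94, 495, 879 and 910 of 1000 each, with 87 false among 2465. A simulated 2-fold rise of the cholesterol list ranked 1 among the lists, with 0 other lists called. Genes were drawn independently in these simulations, so they do not test the list calls where genes correlate. No library was left out of the comparisons, and 15772 genes entered the fit without a filter and 10147 with the stricter one.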

Results

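RNA was sequenced from astrocytes sorted by fluorescence from the cerebral cortex of wild-type C57BL/6J mice. Stroke was produced by tying off the distal middle cerebral artery for good and then closing both common carotid arteries for 7 min, and sham mice had a lesion of the skull surface alone. The 12 libraries form 6 groups of n = 2, namely sham and days 1, 3, 7, 21 and 60 after the occlusion. Replicate 1 of each group holds 13006008 to 16575045 counts and replicate 2 holds 97056596 to 156128922. The surface marker used for the sort is not stated, and replicates are not stated to be separate animals, so every p-value here measures only the spread between these samples. Fold changes are log2 values ± standard error, levels are CPM as mean ± SD, and n = 2 in each group. For each gene list the members that rose and fell are counted with p adjusted over all genes tested, and then with p adjusted within the list. Intervals and floors cover counting error only.

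Each time after stroke was compared with the same pair of sham libraries to ask how sorted cells differed from those of sham-operated mice, and each time was compared with the time before it to ask when expression moved. The time at which sham cells were taken is not stated, so age and time since surgery may differ from sham along with the time after stroke. Of 15635 genes tested, 4774 differed from sham at day 1 (2606 higher and 2168 lower), 5028 at day 3 (2815 and 2213), 6719 at day 7 (3627 and 3092), 5190 at day 21 (2786 and 2404) and 4929 at day 60 (2621 and 2308). Between neighbouring times 558 genes differed from day 1 to day 3 (483 higher and 75 lower), 983 from day 3 to day 7 (479 and 504), 69 from day 7 to day 21 (38 and 31) and 0 from day 21 to day 60. In the same order, with sham as the reference first, 6696, 6826, 8051, 6923, 6736, 2522, 3857, 2099 and 847 genes had an unadjusted p under 0.05. Scaling with DESeq2 size factors moved the median of all genes against sham by -0.10 to -0.15 log2 units, and it moved the share of changed genes that were higher from 54.6% to 49.8% at day 1, from 55.99% to 51.7% at day 3, from 54.0% to 49.1% at day 7, from 53.7% to 48.6% at day 21 and from 53.2% to 48.6% at day 60. At day 3 more genes were higher than lower under each scaling tried, and at the other times which side was larger depended on the scaling. Changes of single genes and lists below are larger than this shift unless their values say otherwise.

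**Figure D1:**
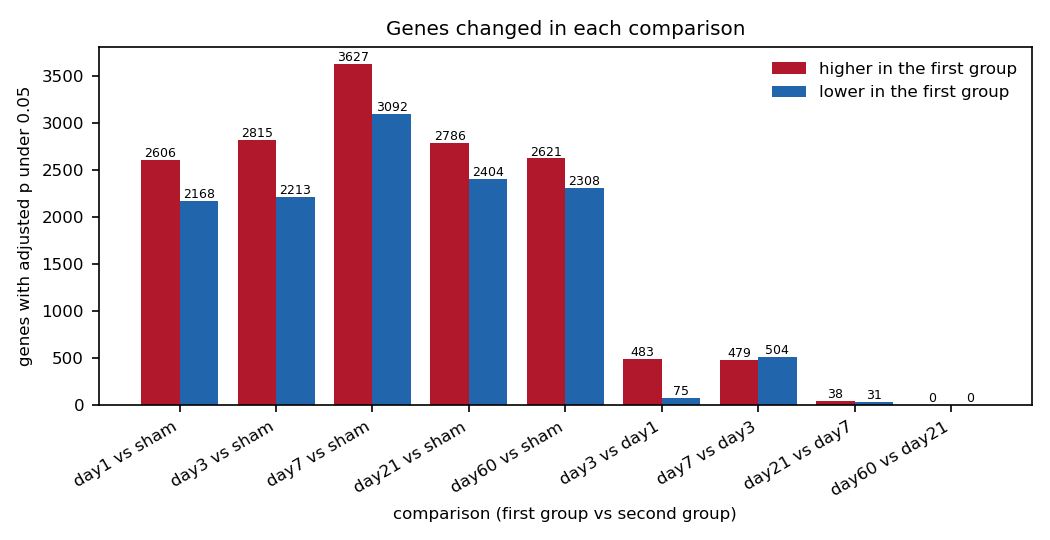
Number of genes with adjusted p under 0.05 in each of the 9 comparisons (x axis, first group against second group); red bars are genes higher and blue bars genes lower in the first group. Counts against sham run from 4774 at day 1 to 6719 at day 7, and the count from day 21 to day 60 is 0.

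On the first principal component, which held 38.0% of the variance, the sham libraries lay at -204.2 and -200.4 and the others between -55.8 and 117.9. On the second, with 17.2%, replicate 1 lay above replicate 2 in all 6 groups. Replicates of a group correlated at 0.879 to 0.939 across genes and libraries of different groups at 0.640 to 0.954, so some libraries were closer to one of another group than to their own replicate.

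Of the 25 landmark genes fixed in advance those of astrocyte reactivity had these levels. Gfap, the intermediate filament protein of astrocytes, stood at 168 ± 9.89 CPM in sham, 1021 ± 817 at day 1, 2806 ± 1891 at day 3, 458 ± 139.5 at day 7, 668 ± 32.1 at day 21 and 182 ± 5.71 at day 60. It rose at day 3 (log2 fold change 4.06 ± 0.69, adjusted p = 0.00237), at day 1 (log2 fold change 2.60 ± 0.65, adjusted p = 0.0144, or 0.0885 without sham replicate 1, 0.0741 without sham replicate 2 and 0.117 without day 1 replicate 2) and at day 21 (log2 fold change 1.99 ± 0.64, adjusted p = 0.0355, or 0.154 without sham replicate 1, 0.124 without sham replicate 2, 0.139 without day 21 replicate 1, 0.0954 without day 21 replicate 2 and 0.0634 without day 60 replicate 1). At day 7 (log2 fold change 1.44 ± 0.62, adjusted p = 0.0865) and day 60 (log2 fold change 0.11 ± 0.61, adjusted p = 0.912) it did not pass. Vim, another intermediate filament gene, rose at all 5 times, from 1.60 ± 0.32 at day 21 up to 3.14 ± 0.34 at day 3. Lcn2, which encodes the siderophore-binding protein lipocalin 2, went from 4.91 ± 0.857 CPM in sham to 308 ± 33.1 at day 1 and 68.05 ± 32.1 at day 3, was 6.16 ± 1.69 at day 7, and reached 1728 ± 543 at day 21 and 1426 ± 102 at day 60. C3, the central complement component, was 0.4996 ± 0.0536 CPM in sham, 1.41 ± 1.52 at day 1, 32.2 ± 8.78 at day 7, 4946 ± 1887 at day 21 and 5135 ± 3012 at day 60. Serpina3n, a serine protease inhibitor, rose at day 1 (log2 fold change 3.91 ± 0.73, adjusted p = 0.00473) and day 3 (log2 fold change 3.61 ± 0.72, adjusted p = 0.00492) and was 5.398 ± 3.58 CPM at day 60 against 5.94 ± 1.98 in sham.

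Stat3, Socs3, Cd44 and Ccl2 were above sham at all 5 times. Stat3, a transcription factor activated by cytokines, was 2.91 ± 0.41 log2 units higher at day 1 and 2.46 ± 0.40 at day 60, and its feedback inhibitor Socs3 5.40 ± 0.86 and 4.78 ± 0.84. Cd44, the hyaluronan receptor, rose by between 3.59 ± 0.40 at day 60 and 5.46 ± 0.44 at day 7. The chemokine Ccl2, which attracts monocytes, was 0.378 ± 0.281 CPM in sham, 311 ± 136 at day 1, 15.4 ± 1.93 at day 7 and 49.2 ± 11.3 at day 60. The glutamate transporter gene Slc1a2 fell at day 7 (log2 fold change -4.36 ± 0.83, adjusted p = 0.00221), with 1039 ± 621 CPM in sham, 517 ± 381 at day 1, 50.7 ± 30.6 at day 7 and 301 ± 213 at day 60. Aqp4, the water channel of astrocyte end-feet, fell at day 7 (log2 fold change -3.11 ± 0.62, adjusted p = 0.00281). In contrast Gja1, which encodes connexin 43, was higher at day 7 (log2 fold change 2.27 ± 0.53, adjusted p = 0.00629, or 0.0554 without sham replicate 2). At day 7 the fibroblast list was also above sham, with a median log2 fold change of 9.07. Which cells carried Gja1 and Cd44 at that time was not tested. Vegfa, the gene of vascular endothelial growth factor, rose at day 1 (log2 fold change 2.86 ± 0.43, adjusted p = 0.00214). In the mm10 (GRCm38) build these genes lie as follows, each annotated as protein-coding. Gfap is on chromosome 11, 102887336 to 102900912, Lcn2 on chromosome 2, 32384633 to 32388252, C3 on chromosome 17, 57203970 to 57228136, Slc1a2 on chromosome 2, 102658659 to 102790784, Mki67 on chromosome 7, 135689784 to 135716361 and the collagen gene Col3a1 on chromosome 1, 45311538 to 45349706.

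**Figure D2:**
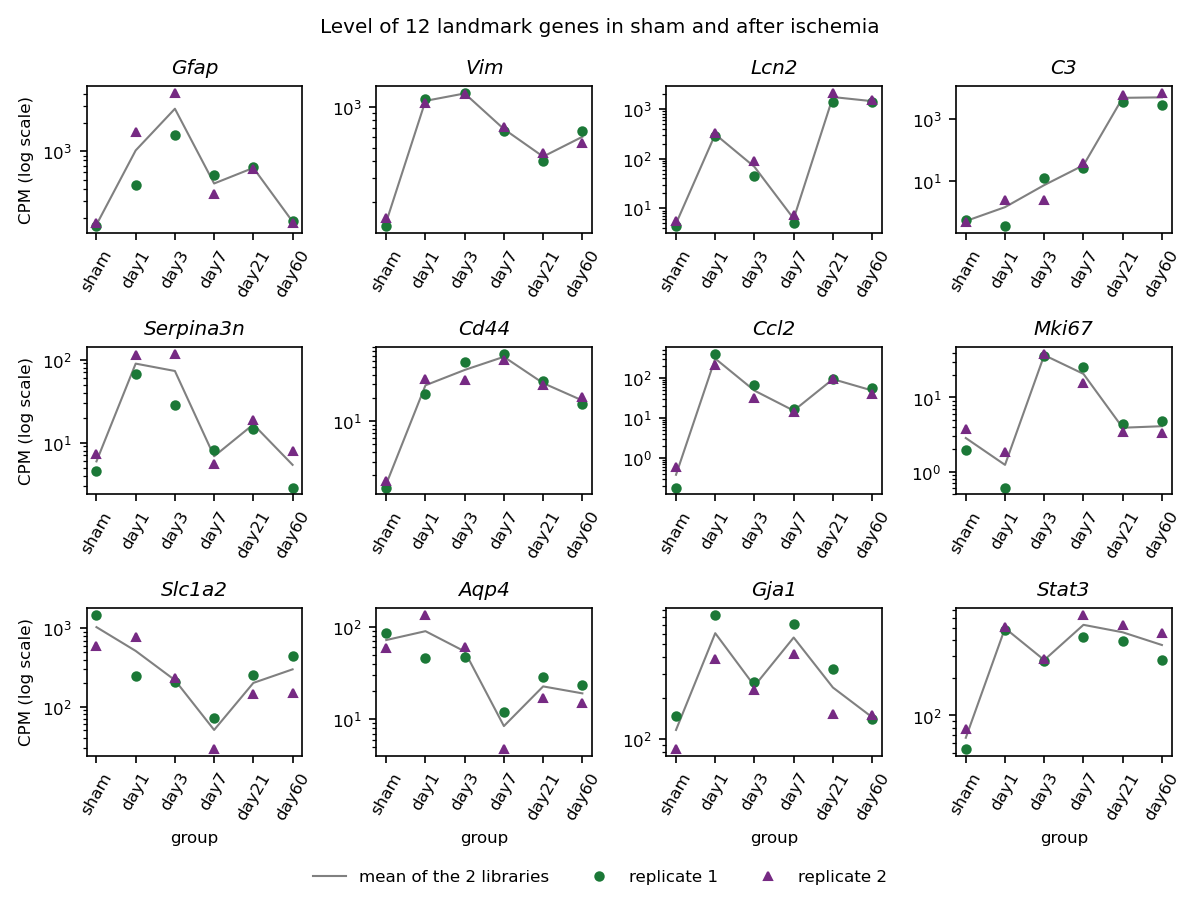
Level of 12 landmark genes in CPM (log axis) by group; circles are replicate 1, triangles replicate 2 and the grey line the mean of both. Lcn2 falls from 308 CPM at day 1 to 6.16 at day 7 and is 1728 at day 21, while Mki67 is highest at day 3 with 37.1 CPM.

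At day 1 the genes with the largest rises included Mmp12, Csf3, Serpinb2 and Mmp3. Mmp12, a metalloproteinase gene, had 0 counts in both sham libraries and 90.8 ± 68.8 CPM at day 1, at least 873-fold higher with a floor of 3 counts per library. Against the same floor Csf3, which encodes granulocyte colony-stimulating factor, was at least 818-fold higher and Serpinb2, an inhibitor of plasminogen activators, at least 564-fold. Mmp3, encoding stromelysin-1, rose from 0.288 ± 0.353 to 992 ± 40.8 CPM (log2 fold change 12.09 ± 1.55, adjusted p = 0.00128). Genes that fell most included Ttr, a carrier of thyroxine and retinol-binding protein (log2 fold change -5.31 ± 1.12, adjusted p = 0.00746), the fructose transporter gene Slc2a5 (log2 fold change -6.23 ± 0.93, adjusted p = 0.00208) and the sodium channel subunit gene Scn4b (log2 fold change -4.76 ± 0.58, adjusted p = 0.000977).

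Reactive-astrocyte lists were higher at day 1. Among pan-reactive genes, 12 of 13 rose, 0 fell and 1 did not pass, or 12 and 0 within the list, with camera adjusted p = 1.03e-10, or 0.0125 with an estimated correlation. Lcn2 rose (log2 fold change 5.97 ± 0.52, adjusted p = 0.000349), and Steap4, a metalloreductase gene, rose by 4.63 ± 0.78. In the A2-associated list, 10 of 12 rose, 0 fell and 2 did not pass, or 10 and 0 within the list, with camera adjusted p = 2.41e-09, or 0.0125 with an estimated correlation. Its members include the transglutaminase gene Tgm1, which rose from 0.119 ± 0.169 to 50.1 ± 37.5 CPM, and the cytokine gene Clcf1 (5.46 ± 0.82). For the A1-associated list, 6 of 11 rose, 0 fell and 5 did not pass, or 6 and 0 within the list, with camera adjusted p = 0.000908, or 0.0561 with an estimated correlation. Of the astrocyte identity and homeostasis genes, 2 of 30 rose, 1 fell and 27 did not pass, or 1 and 0 within the list, with camera adjusted p = 0.64, or 0.912 with an estimated correlation. The list's median of 0.09 and mean of -0.07 lie on either side of 0. Cytoskeletal genes of reactive glia rose as a list (camera adjusted p = 1.75e-07, or 0.0332 with an estimated correlation), and 13 of 21 rose, 0 fell and 8 did not pass, or 13 and 0 within the list, led by the tubulin gene Tubb6 (7.92 ± 0.64) and the membrane linker gene Msn (4.23 ± 0.56).

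Signalling and immune genes moved with them at day 1. Among cytokines and chemokines, 19 of 22 rose, 0 fell and 3 did not pass, or 19 and 1 within the list, with camera adjusted p = 3.67e-16, or 0.0904 with an estimated correlation, including Ccl7 (9.71 ± 0.85), the interleukin gene Il6 (9.31 ± 1.31) and Spp1, which encodes osteopontin (7.17 ± 0.59). Of the JAK-STAT3 and NF-kB regulators, 17 of 21 rose, 0 fell and 4 did not pass, or 18 and 0 within the list, with camera adjusted p = 5.37e-12, or 0.0904 with an estimated correlation. Of the interferon-response genes, 18 of 25 rose, 0 fell and 7 did not pass, or 23 and 0 within the list, with camera adjusted p = 2.41e-09, or 0.0771 with an estimated correlation. Of the immediate early genes, 8 of 18 rose, 0 fell and 10 did not pass, or 10 and 1 within the list, with camera adjusted p = 0.00249, or 0.484 with an estimated correlation. Shares of counts from other cell types moved as well: the endothelium list went from 0.343 ± 0.0721% of counts in sham to 1.14 ± 0.237% at day 1, with Pecam1, an adhesion gene of endothelial cells, at 3.40 ± 0.67. Of that list, 8 of 15 rose, 0 fell and 7 did not pass, or 8 and 0 within the list, with camera adjusted p = 0.00147, or 0.484 with an estimated correlation. Infiltrating-leukocyte markers went from 0.0216 ± 0.0175% to 0.1104 ± 0.0502%, and microglia markers from 0.112 ± 0.007601% to 0.0769 ± 0.00245%.

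Lists of stress and metabolism genes differed at day 1 in how many members changed. Of the antioxidant and metallothionein list, 9 of 18 rose, 2 fell and 7 did not pass, or 9 and 2 within the list, with camera adjusted p = 0.00055, or 0.0476 with an estimated correlation. Hmox1, which encodes heme oxygenase 1, rose from 3.83 ± 0.328 to 738 ± 152 CPM, and the cystine transporter gene Slc7a11 rose by 4.41 ± 0.54. In the list of endoplasmic reticulum stress, 12 of 18 rose, 0 fell and 6 did not pass, or 12 and 0 within the list, with camera adjusted p = 0.000566, or 0.0943 with an estimated correlation. The chaperone gene Hspa5 rose by 3.03 ± 0.39. Of the heat shock genes, 6 of 14 rose, 0 fell and 8 did not pass, or 7 and 0 within the list, with camera adjusted p = 0.0134, or 0.132 with an estimated correlation. Of the cholesterol synthesis genes, 6 of 22 rose, 0 fell and 16 did not pass, or 7 and 0 within the list, with camera adjusted p = 0.00879, or 0.135 without day 1 replicate 2, or 0.256 with an estimated correlation. Members that rose include the enzyme genes Sqle (1.72 ± 0.32) and Hsd17b7 (2.04 ± 0.39). Of the nuclear-encoded respiration genes, 0 of 23 rose, 8 fell and 15 did not pass, or 0 and 8 within the list, with camera adjusted p = 0.00385, or 0.054 without day 1 replicate 1, or 0.484 with an estimated correlation. Cox6c, a subunit of cytochrome c oxidase, fell (log2 fold change -3.19 ± 0.54, adjusted p = 0.00332). Of the glycolysis and lactate genes, 5 of 18 rose, 0 fell and 13 did not pass, or 5 and 0 within the list, with camera adjusted p = 0.197, or 0.484 with an estimated correlation. The list's largest rise was in the lactate exporter gene Slc16a3 (3.84 ± 0.60), which is no glycolytic enzyme. Of the hypoxia list, 6 of 18 rose, 3 fell and 9 did not pass, or 7 and 3 within the list, with camera adjusted p = 0.303, or 0.679 with an estimated correlation. Adm, encoding the vasodilator adrenomedullin, rose by 6.70 ± 0.72.

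With the preset correlation of 0.01, matrix genes had the smallest list p at day 1. In the extracellular matrix and protease list, 24 of 28 rose, 0 fell and 4 did not pass, or 26 and 0 within the list, with camera adjusted p = 1.86e-20, or 0.0297 with an estimated correlation. Tnc, which encodes tenascin C, rose by 8.39 ± 0.73. Over the same interval the fibroblast list went from 0.00922 ± 0.000662% to 0.242 ± 0.0528% of counts. Of its genes, 11 of 13 rose, 0 fell and 2 did not pass, or 11 and 0 within the list, with camera adjusted p = 6.72e-08, or 0.166 with an estimated correlation. Lum, the gene of the collagen-binding protein lumican, rose by 7.49 ± 0.66. The neuron list went from 1.28 ± 0.0725% to 0.1701 ± 0.113%, where 0 of 17 rose, 13 fell and 4 did not pass, or 0 and 15 within the list, with camera adjusted p = 8.24e-09, or 0.0904 with an estimated correlation. In sham, 17 of these 17 neuron genes had at least 1 CPM and 16 at least 10 CPM. Whether falls of neuronal genes below sham, here and later, came from astrocytes or from neurons carried through the sort was not tested. The test, median and mean of the neural stem cell list differed in sign at day 1 (test up, -0.34 and -0.13). Of its genes, 7 of 20 rose, 4 fell and 9 did not pass, or 8 and 6 within the list, with camera adjusted p = 0.87, or 0.912 with an estimated correlation. Without day 1 replicate 1 the number of changed genes was 1954, without sham replicate 1 it was 2336 and without sham replicate 2 it was 2500. Leaving out at least 1 of the 12 libraries ended 51 of the 142 calls of named genes and 5 of the 22 calls of lists. Where a call named in any comparison with sham ended in this way, the adjusted p without that library stands beside it.

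At day 3 the changes included genes of dividing cells and of macrophages. Cd5l, which encodes a secreted protein of macrophages, had 0 counts in sham and 49.7 ± 10.2 CPM at day 3, at least 478-fold higher. Mmp12 was at least 277-fold higher, and the kininogen genes Kng1 and Kng2 at least 112-fold and 120.1-fold. Lilrb4, an inhibitory receptor gene of myeloid cells, rose from 0.137 ± 0.0244 to 249 ± 194 CPM (log2 fold change 10.74 ± 1.27, adjusted p = 0.00045). Among the largest falls were the serotonin receptor gene Htr7 (log2 fold change -5.13 ± 1.01, adjusted p = 0.00458) and Scn4b (log2 fold change -5.71 ± 0.62, adjusted p = 0.000307).

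Cell division genes rose together at day 3. Of that list, 29 of 30 rose, 0 fell and 1 did not pass, or 30 and 0 within the list, with camera adjusted p = 1.48e-18, or 0.121 with an estimated correlation. The mitotic cyclin gene Ccnb2 rose from 1.74 ± 0.755 to 74.96 ± 33.1 CPM, the cyclin-dependent kinase gene Cdk1 by 4.68 ± 0.77, and the proliferation marker Mki67 by 3.69 ± 0.60. Microglia markers moved in the same comparison, from 0.112 ± 0.007601% to 0.994 ± 0.345% of counts, where 14 of 19 rose, 0 fell and 5 did not pass, or 15 and 0 within the list, with camera adjusted p = 1.02e-07, or 0.13 with an estimated correlation. Cd68, a lysosomal gene of phagocytes, rose by 5.27 ± 0.43 and the microglial signalling adaptor gene Tyrobp by 3.88 ± 0.48. Leukocyte markers went from 0.0216 ± 0.0175% to 0.555 ± 0.128%, where 13 of 19 rose, 0 fell and 6 did not pass, or 13 and 0 within the list, with camera adjusted p = 4.45e-08, or 0.054 with an estimated correlation. Their median log2 fold change was 5.70 as fitted and 3.83 with members at 0 counts set to their bound. Lyz2, the lysozyme gene of myeloid cells, rose by 8.10 ± 0.72, and the arginase gene Arg1 by 9.39 ± 1.59.

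The reactive lists stayed above sham at day 3. Of the pan-reactive genes, 11 of 13 rose, 0 fell and 2 did not pass, or 12 and 0 within the list, with camera adjusted p = 8.49e-09, or 0.0221 with an estimated correlation. In the cytoskeleton list, 14 of 21 rose, 0 fell and 7 did not pass, or 16 and 0 within the list, with camera adjusted p = 8.49e-09, or 0.0221 with an estimated correlation. The galectin gene Lgals3 rose by 8.08 ± 0.54. For cytokines and chemokines, 18 of 22 rose, 0 fell and 4 did not pass, or 18 and 0 within the list, with camera adjusted p = 1.12e-16, or 0.115 with an estimated correlation. Tnf, the gene of tumor necrosis factor, rose by 8.42 ± 0.73. Of the MHC class II genes, 5 of 7 rose, 0 fell and 2 did not pass, or 5 and 0 within the list, with camera adjusted p = 0.000387, or 0.148 with an estimated correlation. Cd74, the invariant chain, rose by 5.78 ± 0.60. Of the astrocyte identity genes, 0 of 30 rose, 7 fell and 23 did not pass, or 0 and 5 within the list, with camera adjusted p = 0.00151, or 0.498 with an estimated correlation. The glypican gene Gpc5 fell (log2 fold change -2.46 ± 0.46, adjusted p = 0.0035). For the glutamate, GABA, potassium and water list, 1 of 21 rose, 6 fell and 14 did not pass, or 1 and 7 within the list, with camera adjusted p = 0.0118, or 0.498 with an estimated correlation. The GABA receptor gene Gabbr2 fell (log2 fold change -4.06 ± 0.88, adjusted p = 0.00699). The fibroblast list reached 1.61 ± 1.26% of counts, the endothelium list 0.568 ± 0.414% and the neuron list 0.1295 ± 0.0549%. Without sham replicate 1 the number of changed genes was 2941, without sham replicate 2 it was 2969 and without day 3 replicate 1 it was 3165. At least 1 library left out ended 42 of 149 calls of named genes and 3 of 24 calls of lists.

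At day 7 collagen and other matrix genes were far above sham and astrocyte identity genes below it. Col3a1, the gene of type III collagen, went from 15.1 ± 0.462 CPM in sham to 82596 ± 66278 at day 7 (log2 fold change 12.42 ± 1.58, adjusted p = 0.00028), and the type I collagen genes Col1a1 and Col1a2 rose by 13.15 ± 2.02 and 11.37 ± 1.47. Nox4, an NADPH oxidase gene, had 0 counts in sham and was at least 482-fold higher, Cd5l at least 518-fold and Siglec1, a sialic acid receptor gene of macrophages, at least 327-fold. Ltbp2, which encodes a protein that binds fibrillin, had 1 count in sham and 411 ± 77.9 CPM at day 7. Among the largest falls, Alas2, the first enzyme of heme synthesis in red blood cells, fell (log2 fold change -7.40 ± 0.86, adjusted p = 0.000182), as did the G protein gene Gng13 (log2 fold change -7.39 ± 1.09, adjusted p = 0.000576) and Otof, which encodes otoferlin (log2 fold change -7.00 ± 1.12, adjusted p = 0.000868).

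Of the extracellular matrix and protease genes at day 7, 26 of 28 rose, 0 fell and 2 did not pass, or 27 and 0 within the list, with camera adjusted p = 8.81e-23, or 0.0765 with an estimated correlation. Mmp2, a gelatinase gene, rose by 10.07 ± 0.90. The fibroblast list moved in the same comparison, from 0.00922 ± 0.000662% of counts in sham to 14.2 ± 8.35% at day 7, with 8.35% in replicate 1 and 20.2% in replicate 2. Of its genes, 13 of 13 rose, 0 fell and 0 did not pass, or 13 and 0 within the list, with camera adjusted p = 6.88e-14, or 0.13 with an estimated correlation. In sham, 11 of its 13 genes had at least 1 CPM and 5 at least 10 CPM. For chondroitin sulfate proteoglycans, 8 of 15 rose, 4 fell and 3 did not pass, or 8 and 4 within the list, with camera adjusted p = 0.0922, or 0.273 with an estimated correlation. The versican gene Vcan rose by 5.72 ± 0.88 while Cspg5 fell (log2 fold change -3.79 ± 0.63, adjusted p = 0.00103). Of the synapse-modulating secreted factors, 9 of 14 rose, 3 fell and 2 did not pass, or 9 and 4 within the list, with camera adjusted p = 0.00325, or 0.207 with an estimated correlation, where the thrombospondin genes Thbs2 (8.75 ± 0.69) and Thbs1 (6.14 ± 0.63) rose and Gpc5 fell (log2 fold change -4.60 ± 0.51, adjusted p = 0.000141). Of the pericyte and smooth muscle list, 5 of 12 rose, 3 fell and 4 did not pass, or 5 and 3 within the list, with camera adjusted p = 0.273, or 0.627 with an estimated correlation. Its member Pdgfrb, a growth factor receptor gene that fibroblasts also express, rose by 6.44 ± 0.52.

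Identity and transport genes of astrocytes fell at day 7. In the identity list, 2 of 30 rose, 21 fell and 7 did not pass, or 2 and 23 within the list, with camera adjusted p = 2e-06, or 0.285 with an estimated correlation. Its members with the largest falls were the tight junction gene Cldn10 (log2 fold change -5.45 ± 0.74, adjusted p = 0.00038), the neurotensin receptor gene Ntsr2 (log2 fold change -4.85 ± 0.60, adjusted p = 0.000249) and the GABA transporter gene Slc6a11 (log2 fold change -4.67 ± 0.67, adjusted p = 0.000514). The list took 2.82 ± 0.402% of counts in sham and 1.47 ± 0.741% at day 7. Most of the day 7 share came from its member Apoe, at 12253 ± 5939 CPM. The median log2 fold change of the list was -3.00, a larger fall than that of the share. For glutamate, GABA, potassium and water handling, 3 of 21 rose, 14 fell and 4 did not pass, or 3 and 15 within the list, with camera adjusted p = 0.000183, or 0.285 with an estimated correlation. Neuron markers fell over the same interval, from 1.28 ± 0.0725% to 0.0297 ± 0.0124% of counts, where 0 of 17 rose, 17 fell and 0 did not pass, or 0 and 17 within the list, with camera adjusted p = 2.4e-13, or 0.0861 with an estimated correlation. Snap25, a synaptic vesicle fusion gene, fell (log2 fold change -5.89 ± 0.40, adjusted p = 3.07e-05). Oligodendrocyte markers went from 1.02 ± 0.0945% to 0.1196 ± 0.0401%, where 2 of 16 rose, 6 fell and 8 did not pass, or 2 and 8 within the list, with camera adjusted p = 0.0195, or 0.371 with an estimated correlation. Among neural stem cell and neurogenic genes, 4 of 20 rose, 7 fell and 9 did not pass, or 4 and 7 within the list, with camera adjusted p = 0.12, or 0.312 with an estimated correlation. The Notch target Hes5 fell (log2 fold change -6.11 ± 0.83, adjusted p = 0.00038) and the growth factor receptor gene Egfr rose by 4.60 ± 0.54.

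More cholesterol synthesis and respiration genes fell than rose at day 7. Of the cholesterol synthesis genes, 2 of 22 rose, 12 fell and 8 did not pass, or 2 and 13 within the list, with camera adjusted p = 0.0031, or 0.215 with an estimated correlation. In the respiration list, 0 of 23 rose, 14 fell and 9 did not pass, or 0 and 14 within the list, with camera adjusted p = 2.47e-05, or 0.312 with an estimated correlation. The share of counts in ribosomal protein genes was also lower, with 0.62% and 0.68% in the sham libraries, 0.16% and 0.15% at day 7 and 0.16% and 0.18% at day 21. Of the antioxidant and metallothionein list, 3 of 18 rose, 7 fell and 8 did not pass, or 3 and 7 within the list, with camera adjusted p = 0.131, or 0.247 with an estimated correlation. The metallothionein genes Mt3 (log2 fold change -6.61 ± 0.94, adjusted p = 0.000481) and Mt1 (log2 fold change -4.76 ± 0.50, adjusted p = 0.000108) fell while Hmox1 rose by 4.79 ± 0.37. Of the glycolysis and lactate genes, 4 of 18 rose, 5 fell and 9 did not pass, or 4 and 5 within the list, with camera adjusted p = 0.839, or 0.893 with an estimated correlation. Their median was -0.70 and their mean -0.08, and by fry the direction was up. Members that rose include the lactate exporter gene Slc16a3 (4.16 ± 0.61), the hexokinase gene Hk2 (3.24 ± 0.64) and Pfkfb3 (2.94 ± 0.43), a regulator of glycolytic flux. The heat shock list had a median of -0.20 and a mean of 0.04. Of its genes, 2 of 14 rose, 3 fell and 9 did not pass, or 2 and 3 within the list, with camera adjusted p = 0.788, or 0.831 with an estimated correlation. For oligodendrocyte precursor markers the camera direction was down and the fry direction up, and, 2 of 12 rose, 2 fell and 8 did not pass, or 2 and 2 within the list, with camera adjusted p = 0.933, or 0.964 with an estimated correlation.

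Phagocytosis and immune lists were above sham at day 7. Of the astrocyte phagocytosis genes, 9 of 14 rose, 0 fell and 5 did not pass, or 10 and 0 within the list, with camera adjusted p = 0.000103, or 0.169 with an estimated correlation. The engulfment receptor gene Megf10 rose by 4.44 ± 0.49 and the cholesterol exporter gene Abca1 by 5.03 ± 0.50. Microglia markers stood at 0.945 ± 0.435% of counts and leukocyte markers at 0.729 ± 0.00423%. The leukocyte list includes Fn1, which is also on the matrix list, so its share can rise with matrix genes. Of the MHC class I genes, 11 of 16 rose, 0 fell and 5 did not pass, or 11 and 0 within the list, with camera adjusted p = 9.44e-05, or 0.169 with an estimated correlation. The peptide transporter gene Tap1 rose by 4.41 ± 0.36. Of the red blood cell markers, 0 of 3 rose, 2 fell and 1 did not pass, or 0 and 3 within the list, with camera adjusted p = 0.0184, or 0.247 with an estimated correlation. That call ended with the replicate number as a block. No list call at day 7 held with an estimated correlation, and no single library left out ended one. Without day 7 replicate 2 the number of changed genes was 4476, and leaving out at least 1 library ended 20 of 151 calls of named genes.

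At day 21 complement genes were far above sham. C3 rose from 0.4996 ± 0.0536 to 4946 ± 1887 CPM (log2 fold change 13.28 ± 1.47, adjusted p = 0.000219), and Serping1, the inhibitor of complement C1, by 8.57 ± 0.57. C6, a part of the membrane attack complex, had 0 counts in sham and was at least 1085-fold higher, the serum amyloid gene Saa4 at least 706-fold and Kng2 at least 502-fold. Cxcl13, the chemokine that attracts B cells, had 1 count in sham and 326 ± 45.5 CPM at day 21. Genes that fell most include Mt3 (log2 fold change -4.75 ± 0.86, adjusted p = 0.00275) and the potassium channel gene Kcnv1 (log2 fold change -4.47 ± 0.63, adjusted p = 0.000747).

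In the complement list at day 21, 8 of 12 rose, 0 fell and 4 did not pass, or 10 and 1 within the list, with camera adjusted p = 3.14e-06, or 0.124 with an estimated correlation, and a median of 5.89 with members at 0 counts at their bound. C4b, another complement gene, had 10.02 ± 12.3 CPM in sham and 14185 ± 18411 at day 21, and in all 6 groups it was at least 8-fold higher in replicate 2 than in replicate 1. How reads that match several genes were counted is not stated, so the level of C4b and the share of counts in the complement list are uncertain. Of the pan-reactive genes, 10 of 13 rose, 0 fell and 3 did not pass, or 10 and 0 within the list, with camera adjusted p = 3.37e-10, or 0.0156 with an estimated correlation, led by Steap4 (10.20 ± 0.98), Lcn2 (8.46 ± 0.59) and the ceruloplasmin gene Cp (5.68 ± 0.65). In the A1-associated list, 6 of 11 rose, 0 fell and 5 did not pass, or 6 and 0 within the list, with camera adjusted p = 4.42e-05, or 0.0477 with an estimated correlation. For the interferon response, 24 of 25 rose, 0 fell and 1 did not pass, or 25 and 0 within the list, with camera adjusted p = 1.27e-12, or 0.0522 with an estimated correlation. The interferon regulator gene Irf7 rose by 4.38 ± 0.43. Over the same comparison the fibroblast list was at 4.13 ± 1.28% of counts, where 13 of 13 rose, 0 fell and 0 did not pass, or 13 and 0 within the list, with camera adjusted p = 3.71e-17, or 0.0739 with an estimated correlation. Leukocyte markers were at 0.295 ± 0.0705%. Most of that share came from Lyz2, at 1646 ± 753 CPM, and from Fn1, also on the matrix list, at 1129 ± 269 CPM.

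Of the respiration and identity genes, more were called lower than higher at day 21. Of the nuclear-encoded respiration genes, 0 of 23 rose, 13 fell and 10 did not pass, or 0 and 15 within the list, with camera adjusted p = 3e-07, or 0.315 with an estimated correlation. Cox6c fell (log2 fold change -3.99 ± 0.56, adjusted p = 0.000777). Of the astrocyte identity genes, 1 of 30 rose, 11 fell and 18 did not pass, or 1 and 14 within the list, with camera adjusted p = 0.00153, or 0.517 with an estimated correlation. Cldn10 fell (log2 fold change -3.48 ± 0.67, adjusted p = 0.00369). Neuron markers were at 0.154 ± 0.00782% of counts against 1.28 ± 0.0725% in sham, where 0 of 17 rose, 14 fell and 3 did not pass, or 0 and 16 within the list, with camera adjusted p = 1.46e-08, or 0.109 with an estimated correlation, and oligodendrocyte markers at 0.347 ± 0.0306% against 1.02 ± 0.0945%, where 3 of 16 rose, 5 fell and 8 did not pass, or 3 and 5 within the list, with camera adjusted p = 0.156, or 0.657 with an estimated correlation. Cell division genes did not pass (5 of 30 rose, 0 fell and 25 did not pass, or 0 and 0 within the list, with camera adjusted p = 0.659, or 0.939 with an estimated correlation). Signs differed for the neural stem cell list (median 0.08, mean -0.26, test down) and the heat shock list (median 0.24, mean 0.26, test down). Without day 21 replicate 2 the number of changed genes was 2628, without day 21 replicate 1 it was 2774, without sham replicate 1 it was 2962 and without sham replicate 2 it was 3406. At least 1 library left out ended 39 of 149 calls of named genes and 1 of 22 calls of lists, and the replicate block ended that of the T cell gene Cd8a, which had 0 counts in sham.

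At day 60 complement, antigen presentation and interferon genes were above sham. C6 was at least 1800.4-fold higher and C3 stood at 5135 ± 3012 CPM (log2 fold change 13.34 ± 1.47, adjusted p = 0.000225). In the complement list, 8 of 12 rose, 0 fell and 4 did not pass, or 9 and 1 within the list, with camera adjusted p = 1.74e-06, or 0.124 with an estimated correlation. Its share of counts was 1.28% in one day 60 library and 6.996% in the other. Cxcl13 reached 875 ± 209.8 CPM, Mmp12 was at least 1046-fold higher and Cd5l at least 876-fold. The MHC class II gene H2-Ab1 rose from 0.5197 ± 0.313 to 401 ± 81.2 CPM (log2 fold change 9.49 ± 0.97, adjusted p = 0.00015). The largest falls include Alas2 (log2 fold change -5.82 ± 0.80, adjusted p = 0.000728), Fezf2, a transcription factor gene of deep-layer projection neurons (log2 fold change -4.57 ± 0.89, adjusted p = 0.00452), and Plagl1, a zinc finger gene (log2 fold change -4.53 ± 0.67, adjusted p = 0.00113).

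Of the MHC class II genes at day 60, 5 of 7 rose, 0 fell and 2 did not pass, or 6 and 0 within the list, with camera adjusted p = 4.01e-07, or 0.0813 with an estimated correlation. Of the MHC class I genes, 12 of 16 rose, 0 fell and 4 did not pass, or 14 and 0 within the list, with camera adjusted p = 2.31e-09, or 0.0475 with an estimated correlation. Of the interferon-response genes, 24 of 25 rose, 0 fell and 1 did not pass, or 24 and 0 within the list, with camera adjusted p = 4.01e-16, or 0.0341 with an estimated correlation. Leukocyte markers moved with them at 0.209 ± 0.0365% of counts against 0.0216 ± 0.0175% in sham, where 10 of 19 rose, 0 fell and 9 did not pass, or 13 and 1 within the list, with camera adjusted p = 2.98e-05, or 0.0942 with an estimated correlation, while the microglia list did not pass (4 of 19 rose, 4 fell and 11 did not pass, or 6 and 4 within the list, with camera adjusted p = 0.955, or 0.985 with an estimated correlation). Most of the leukocyte share at day 60 came from Lyz2, at 1458 ± 328 CPM, and from Fn1, also on the matrix list, at 507 ± 235 CPM. In the microglia list P2ry12, a receptor gene of resting microglia, fell (log2 fold change -4.48 ± 0.61, adjusted p = 0.000686) and Cd68 rose by 2.47 ± 0.38. Of the cholesterol synthesis genes, 1 of 22 rose, 8 fell and 13 did not pass, or 1 and 11 within the list, with camera adjusted p = 0.000676, or 0.151 with an estimated correlation. The squalene epoxidase gene Sqle fell (log2 fold change -2.50 ± 0.33, adjusted p = 0.000584). Of the identity genes, 1 of 30 rose, 9 fell and 20 did not pass, or 1 and 10 within the list, with camera adjusted p = 0.00568, or 0.604 with an estimated correlation. Gpc5 fell (log2 fold change -2.45 ± 0.46, adjusted p = 0.00365) and the connexin 30 gene Gjb6 rose by 2.32 ± 0.40. The fibroblast list was at 2.47 ± 0.487% of counts and the neuron list at 0.166 ± 0.0449%. Antioxidant genes had a median of -0.16 and a mean of -0.07 where the test pointed up (adjusted p = 0.986). Without sham replicate 1 the number of changed genes was 2654, without day 60 replicate 2 it was 2730 and without sham replicate 2 it was 2793. At least 1 library left out ended 43 of 149 calls of named genes and 1 of 22 calls of lists.

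**Figure D3:**
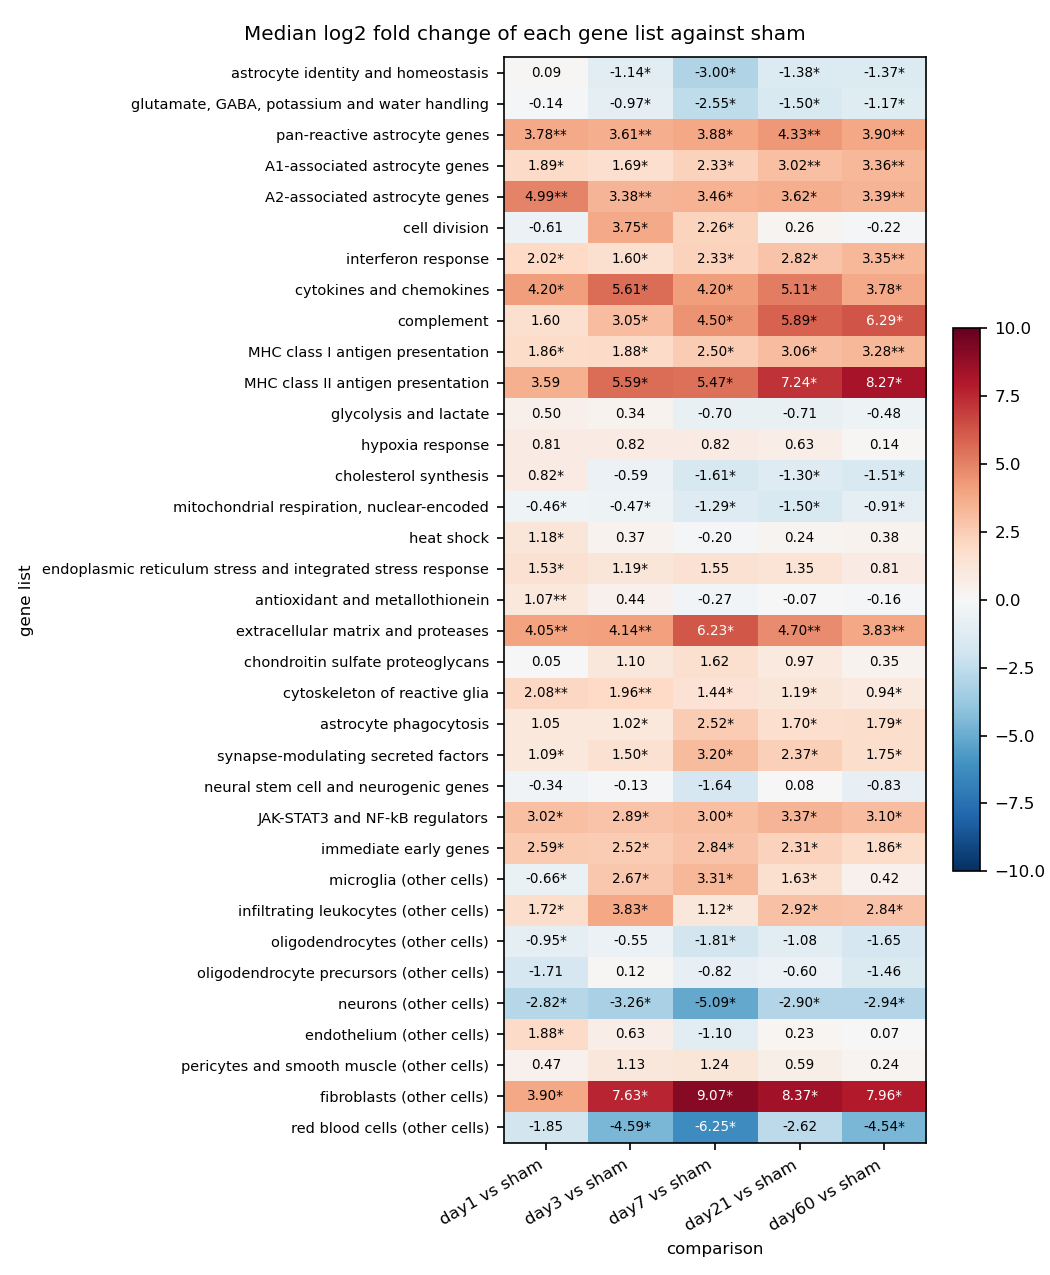
Median log2 fold change against sham of the 35 gene lists (y axis) at each of the 5 times (x axis), with members at 0 counts in a group set to their bound; 1 star marks a camera adjusted p under 0.05 and a pair of stars a call that also passed with an estimated correlation. The fibroblast list has the highest median, 9.07 at day 7, and the cell division list is at 3.75 at day 3 and -0.22 at day 60.

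**Figure D4:**
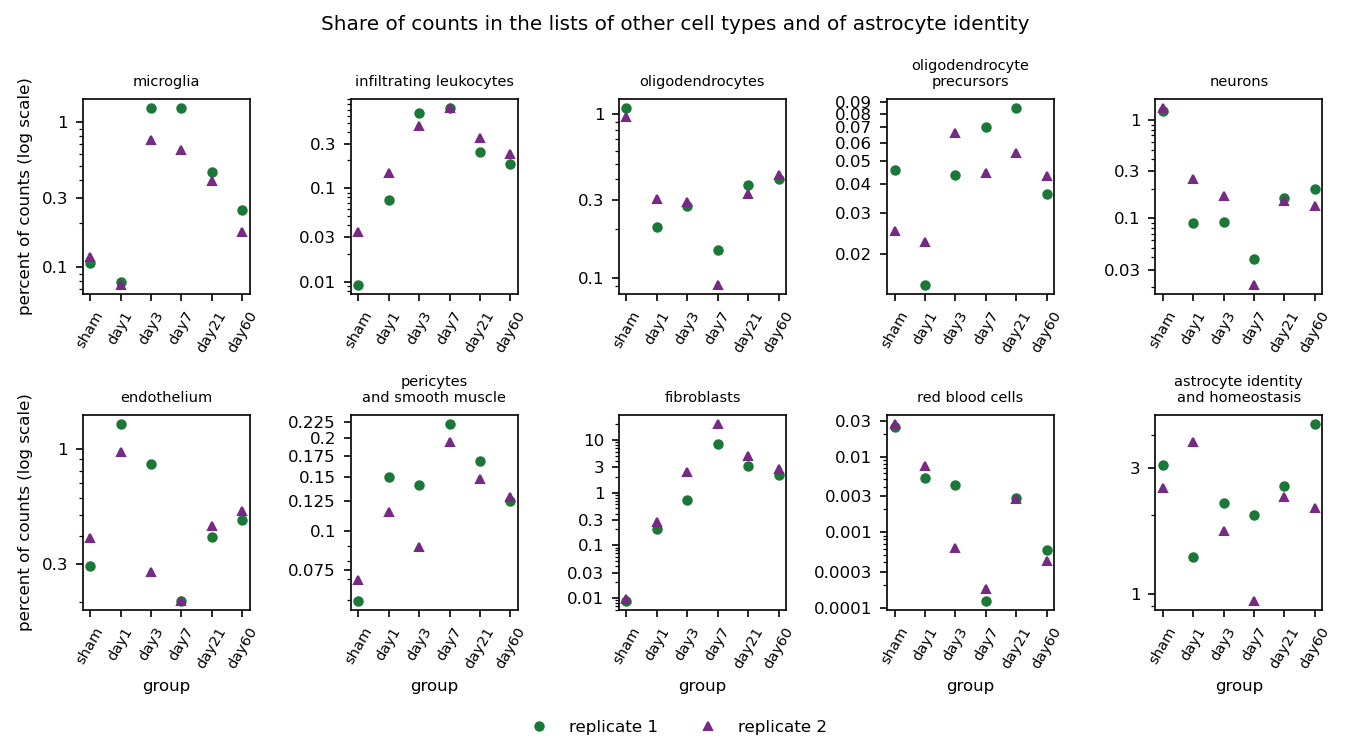
Percent of counts (log axis) in the lists of 9 other cell types and in the astrocyte identity list, by group; circles are replicate 1 and triangles replicate 2. The fibroblast list rises from 0.00922% in sham to 14.2% at day 7, and the neuron list goes from 1.28% to 0.0297%.

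From day 1 to day 3 cell division genes and microglia markers rose. Esco2, a cohesin acetyltransferase gene of dividing cells, had 1 count at day 1 and 11.2 ± 0.775 CPM at day 3, and Cep55, a gene of the last step of cell division, rose by 7.68 ± 1.06. Stc1, which encodes the hormone stanniocalcin 1, fell (log2 fold change -5.55 ± 0.82, adjusted p = 0.00572). Of the cell division list, 24 of 30 rose, 0 fell and 6 did not pass, or 28 and 0 within the list, with camera adjusted p = 4.92e-54, or 0.058 with an estimated correlation. Mki67 rose by 4.85 ± 0.63. Microglia markers rose in the same interval, where 16 of 19 rose, 0 fell and 3 did not pass, or 18 and 0 within the list, with camera adjusted p = 1.01e-35, or 0.0565 with an estimated correlation. Trem2, a lipid receptor gene of microglia, rose by 4.32 ± 0.48 and Lyz2 of the leukocyte list by 4.85 ± 0.62. The sign of median and test differed for MHC class I (0.06, down), hypoxia (0.19, down), synapse-modulating factors (0.16, down) and pericytes (-0.02, up). The 558 changed genes became 239 without day 1 replicate 1, 327 without day 1 replicate 2, 318 without day 3 replicate 2 and 362 without day 21 replicate 2. With the replicate block the count was 1313. At least 1 library left out ended 41 of 61 calls of named genes and 6 of 14 calls of lists.

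From day 3 to day 7 matrix genes rose, and antioxidant and metallothionein genes fell. Mmp2 rose from 138 ± 133 to 1568 ± 142 CPM, and the collagen gene Col8a1 from 60.01 ± 15.8 to 1387 ± 310.3. S100a8 and S100a9, genes abundant in neutrophils, went from 37.4 ± 3.84 and 34.4 ± 5.08 CPM to 0.739 ± 0.18995 and 0.692 ± 0.219. Lcn2 went from 68.05 ± 32.1 to 6.16 ± 1.69 CPM. Of the matrix list, 14 of 28 rose, 1 fell and 13 did not pass, or 21 and 1 within the list, with camera adjusted p = 2.39e-12, or 0.177 with an estimated correlation, beside fibroblast shares of 1.61% and 14.2%. Of the antioxidant and metallothionein genes, 0 of 18 rose, 10 fell and 8 did not pass, or 0 and 13 within the list, with camera adjusted p = 3.25e-09, or 0.0169 with an estimated correlation. Mt1 went from 426 ± 4.86 to 31.8 ± 0.227 CPM. Signs of median, mean and test differed for MHC class II (-0.12, -0.09, up), pericytes (0.06, -0.01, up) and red blood cells (-0.37, 1.22, down). The 983 changed genes became 0 without day 7 replicate 2, 1 without day 7 replicate 1, 139 without day 3 replicate 1, 592 without day 3 replicate 2, 430 without day 21 replicate 1, 536 without day 21 replicate 2 and 649 without sham replicate 1, so each of the 94 calls of named genes in this comparison was lost when some library was left out. With the replicate block the count was 2853, and 8 of the 19 calls of lists ended when a library was left out.

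From day 7 to day 21 Cxcl5 and Lcn2 rose while the share of fibroblast genes was lower. Cxcl5, a chemokine gene that attracts neutrophils, went from 0.277 ± 0.107 to 422 ± 90.9 CPM (log2 fold change 10.45 ± 0.70, adjusted p = 0.000428), and Lcn2 from 6.16 ± 1.69 to 1728 ± 543 CPM (log2 fold change 8.13 ± 0.58, adjusted p = 0.000428). C3 went from 32.2 ± 8.78 to 4946 ± 1887 CPM and the serum amyloid gene Saa3 from 2.78 ± 0.613 to 540.0 ± 178. Spp1 went from 28747 ± 458 to 2005 ± 31.7 CPM and Tnc from 70.1 ± 12.1 to 6.59 ± 0.499. The fibroblast list had 14.2% of counts at day 7 and 4.13% at day 21. Of the cell division genes, 0 of 30 rose, 2 fell and 28 did not pass, or 0 and 24 within the list, with camera adjusted p = 1.89e-23, or 0.133 with an estimated correlation. Of the microglia markers, 0 of 19 rose, 1 fell and 18 did not pass, or 0 and 12 within the list, with camera adjusted p = 4.05e-11, or 0.144 with an estimated correlation. Signs of median, mean and test differed for A2-associated genes (-0.12, 0.11, up), hypoxia (-0.18, 0.15, up), oligodendrocyte precursors (0.30, 0.09, down), endoplasmic reticulum stress (-0.17, 0.02, down) and glycolysis (-0.07, 0.01, down). The 69 changed genes became 2 and 3 without day 7 replicate 1 or 2, 5 and 6 without a day 21 library, 34 without day 60 replicate 1, 42 and 43 without a sham library, 111 and 112 without a day 3 library, and 223 and 228 without a day 1 library. The replicate block gave 635, and among named genes the calls of Cxcl5 and Lcn2 alone held with each library out.

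From day 21 to day 60 edgeR called 0 genes, with a smallest adjusted p of 0.0838, where DESeq2 called 114, limma-voom 12 and edgeR with the replicate block 21. Without either sham or either day 1 library edgeR called 2. The genes with the smallest unadjusted p include Lhx8, a transcription factor gene of forebrain neurons (3.76 ± 0.0116 and 64.7 ± 17.3 CPM, log2 fold change 4.11 ± 0.50, adjusted p = 0.101), Penk, the enkephalin precursor gene (10.2 ± 1.87 and 45.6 ± 10.98 CPM, log2 fold change 2.16 ± 0.37, adjusted p = 0.145), and Fcrls, a microglial gene (118 ± 1.64 and 11.4 ± 0.0554 CPM, log2 fold change -3.38 ± 0.40, adjusted p = 0.0838). By camera the microglia list was lower at day 60 (0 of 19 rose, 0 fell and 19 did not pass, or 0 and 8 within the list, with camera adjusted p = 4.85e-16, or 0.275 with an estimated correlation), and the respiration list was higher (0 of 23 rose, 0 fell and 23 did not pass, or 0 and 0 within the list, with camera adjusted p = 0.000331, or 0.687 with an estimated correlation). Median, mean and test differed in sign for glycolysis (0.10, -0.13, down) and pericytes (-0.08, 0.23, up), and for the glutamate list the test was up beside a mean just below 0. Leaving out at least 1 library ended 7 of the 9 calls of lists.

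Tested over all 6 groups together, 6670 genes differed. Of these 2514 had their highest mean in sham (37.7%) and 1572 at day 7 (23.6%), with 917 at day 1 (1532 with the replicate block), 667 at day 3 (1001 with the block), 570 at day 60 and 430 at day 21. The lowest mean fell in sham for 2656 genes and at day 7 for 1717. Without sham replicate 1 the count of 6670 was 4377, and without sham replicate 2 it was 4432. In all 5 comparisons with sham 1265 genes were higher and 1095 lower. Days 7 and 21 shared 4754 genes changed in the same direction and 8 in opposite directions, and days 1 and 60 shared 3034 and 42, or 4585 in the same direction with the replicate block. Because every time is compared with the same sham libraries, fold changes correlate without any shared effect. Log2 fold changes at different times correlated at 0.671 to 0.881 across genes, which are not independent replicates, against about 0.50 in 20 simulations with no change. The simulated value does not measure what part of the observed correlation came from the shared libraries. The covariance was 3.68 to 6.07 in the data and 0.461 to 0.472 in the simulations. How much the shared sham libraries add to the numbers of shared genes was not measured.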

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

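Of the tests in this part, those of the other-cell medians, of the share of counts in the most abundant genes, and of the ratio of Lcn2 and C3 to the fibroblast genes were chosen after the result was seen. Of the genes called higher than sham at one time and lower at another, 119 also passed a contrast of the 2 times themselves over the 10 pairs of times, and 19 of them are named by the rule above, of which 18 are described here. That number was 39 without sham replicate 1, 39 without sham replicate 2, 79 without day 7 replicate 1 and 270 with the replicate block. For each gene below, the difference is the later time minus the earlier time in log2 units. Opposite calls against sham were required first, so a gene chosen this way was likely to pass the contrast. The adjusted p beside each difference is therefore no separate support for the calls against sham.

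Birc5, Casc5 and Esco2 are expressed in dividing cells, and each was below sham at day 1 and above it at day 3. At day 60 Casc5 (log2 fold change -3.14 ± 0.75, adjusted p = 0.0118) and Esco2 (-5.36 ± 1.16, adjusted p = 0.00725) were below sham again, and Birc5 did not pass (-1.29 ± 0.47, adjusted p = 0.0602). As a list, the cell division genes did not pass at day 1 (4 of 30 rose, 2 fell and 24 did not pass, or 4 and 2 within the list, with camera adjusted p = 0.421, or 0.842 with an estimated correlation), with a median log2 fold change of -0.61 beside 0.0145% of counts in sham and 0.0288% at day 1. Birc5 went from 0.914 CPM at day 1 to 14.3 at day 7 against 3.49 in sham (difference 3.995 ± 0.52, adjusted p = 0.00101). Casc5 had 0.0279 CPM at day 1, 5.04 at day 7 and 1.28 in sham (difference 6.86 ± 0.90, adjusted p = 0.00102), and Esco2 had 0.0278 at day 1, 11.2 at day 3 and 1.53 in sham (difference 9.79 ± 1.41, adjusted p = 0.00512). The fitted differences of Casc5 and Esco2, and below those of Gal, Msln, Lhx8, Car3 and Prlr, depend on the prior count because a group is at or near 0 CPM, so the CPM values carry the result.

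Other genes were above sham at day 1 and below it later. Hsd17b7 went from 54.1 CPM at day 1 to 4.45 at day 7 with 13.2 in sham (difference -3.61 ± 0.41, adjusted p = 0.000668). Sqle was at 148 CPM at day 1, 7.91 at day 60 and 44.96 in sham (difference -4.22 ± 0.36, adjusted p = 0.000386). Asns, which makes asparagine, was at 126 CPM at day 1, 13.1 at day 60 and 63.6 in sham (difference -3.27 ± 0.31, adjusted p = 0.00047).

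Aif1 had 4.83 CPM at day 1, 83.6 at day 3 and 15.5 in sham (difference 4.10 ± 0.54, adjusted p = 0.00336). Fcrls had 582 CPM at day 7, 11.4 at day 60 and 43.4 in sham (difference -5.68 ± 0.44, adjusted p = 0.000709). S100a9 had 34.4 CPM at day 3, 0.692 ± 0.219 at day 7 and 3.48 ± 3.45 in sham (difference -5.59 ± 0.90, adjusted p = 0.0127), and Ly6a had 1469 at day 1, 71.97 at day 7 and 273 in sham (difference -4.35 ± 0.63, adjusted p = 0.00165).

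Gal, the galanin gene, had 41.8 CPM at day 7, 0 at day 60 and 0.0962 ± 0.136 in sham (difference -14.40 ± 1.80, adjusted p = 0.00586), and Msln had 37.1 at day 1, 0 at day 60 and 1.76 in sham (difference -14.23 ± 1.06, adjusted p = 0.000386). The sham level of Gal lies under the sham floor of 0.104 CPM, so a fall of Gal below sham at day 60 is not shown by its levels. Penk had 65.2 CPM at day 3, 10.2 at day 21 and 22.2 in sham (difference -2.68 ± 0.37, adjusted p = 0.00752). Aspn had 55.9 CPM at day 7, 3.003 at day 60 and 13.1 in sham (difference -4.21 ± 0.38, adjusted p = 0.00196), and Crabp1 had 22.2 at day 1, 0.162 at day 7 and 1.15 in sham (difference -7.57 ± 0.77, adjusted p = 0.000477).

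Lhx8 was below sham at days 1, 3 and 7 and above it at days 21 and 60, and Car3 was below it at day 7 and above it at day 60. Lhx8 had 0 CPM at day 1, 64.7 at day 60 and 0.427 in sham (difference 15.04 ± 0.94, adjusted p = 0.000458). Car3, a carbonic anhydrase gene, had 0.0336 CPM at day 7, 111 at day 60 and 0.696 in sham (difference 13.25 ± 1.58, adjusted p = 0.00473). Prlr, the prolactin receptor gene, had 0.00913 CPM at day 3, 25.8 at day 21, 0 at day 60 and 3.97 ± 4.51 in sham (difference 10.56 ± 1.36, adjusted p = 0.00752).

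All 13 fibroblast genes rose at day 7, when Col3a1, Col1a1 and Col1a2 stood at 82596, 56118 and 44661 CPM. Once replicate 2 was thinned to the depth of replicate 1, 13 of 13 genes were still higher than sham, with a median log2 fold change of 9.38. Sham and day 7 each hold a shallow replicate 1 and a deep replicate 2. Their depths are thus balanced, so thinning was unlikely to remove the rise and says little about its cause. A candidate source is fibroblasts carried through the FACS of astrocytes, a sort meant to remove them, whose marker is not stated. On a list of 20 mesenchymal transcription factors without matrix genes, written before its values were seen, 16 of 18 measured factors (88.9%) were higher than sham and 0 lower, with a median of 4.69, while 11 of the 13 fibroblast genes had at least 1 CPM in sham and 1 is on another list. Astrocytes that express mesenchymal genes after stroke were not tested and stay open.

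The identity genes of astrocytes fell at day 7, with a median log2 fold change of -3.00. A lower share of astrocytes with every other cell type in their place would raise all other-cell lists, but the medians were -5.09 for neurons, -1.81 for oligodendrocytes and -1.10 for endothelium, beside 3.31 for microglia and 9.07 for fibroblasts. The data also argue against a few abundant genes taking the counts, since the 10 most abundant genes held 17.1% of counts in one day 7 library and 30.1% in the other. A share of that size lowers all other genes by at most 0.52 log2 units, and 87.5% of counts would have to be taken to lower them by the median of the list. Without TMM the median of the list was -3.35 to -2.52 over the 4 pairs of a day 7 and a sham library. It stays open that astrocytes may have lowered these genes themselves, or that microglia and fibroblasts replaced part of the sorted astrocytes and neurons. The data hold no measure of cell numbers to weigh these.

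Lcn2 and C3 were high at day 21 and lower at day 7. At day 7 Lcn2, at 6.16 CPM, was near its sham level, while C3, at 32.2 CPM, was already above its own. Fibroblasts holding a fixed amount of Lcn2 and C3 are argued against. Relative to the summed fibroblast list, Lcn2 was 1078.5 times higher at day 21 than at day 7 and C3 580.9 times. The list itself went from 14.2% to 4.13% of counts. These ratios follow from levels already seen, so they are no separate test. They leave open fibroblasts whose amounts of both genes changed. Neutrophils are argued against as well, since S100a8 and S100a9 together reached 0.921% of the Lcn2 level in one day 21 library and 0.634% in the other, at 12.9 CPM against 71.8 CPM at day 3. Astrocytes or another cell type may have raised both genes between the 2 times, and fibroblasts may have changed state. The time after stroke is the difference that the design names, and its effect on astrocytes alone was not tested.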

How the results depend on the processing

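Among the alternatives, thinning of replicate 2, thinning with the replicate block, the fit without the day 7 libraries, and the removal of other-cell and matrix genes from the tests or from the TMM factors were chosen after seeing the data. A count is called steady when it stayed within 1.5 times its value in the report.

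Against sham the number of changed genes was steady under DESeq2 size factors, upper-quartile factors, either filter, the DESeq2 test, limma-voom, the replicate block in edgeR, a log2 fold change of at least 1, the table of the whole series and the later alternatives, and after day 1 also with the 4 libraries compared. It ran from 3992 to 6788 at day 1, 3757 to 6887 at day 3, 5215 to 9095 at day 7, 4397 to 7227 at day 21 and 4037 to 6866 at day 60 over these, where day 7 includes the replicate block in DESeq2. That block moved it to 7716 at day 1, 7745 at day 3, 8033 at day 21 and 7732 at day 60, and to 11120 for the test of all groups (6670), and the cause was not tested. At day 1 the fit of the 4 libraries alone, which has fewer samples, gave 2721. Of the 4774 genes at day 1, 4536 were also called with DESeq2 size factors, 4767 with the replicate block and 2615 with the 4 libraries alone.

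Counts between neighbouring times moved more, and the cause was not tested. From day 1 to day 3 (558) they were 1426 with DESeq2, 854 with limma-voom, 1313 with the replicate block, 2426 with that block in DESeq2, 1363 with block and thinning, 370 without the day 7 libraries and 0 with the 4 libraries alone. From day 3 to day 7 (983) the values in that order were 2618, 1535, 2853, 4294 and 2858, and 0 with the 4 libraries alone. From day 7 to day 21 (69) they were 1047, 287, 635, 1824 and 646, and 350 with the 4 libraries alone. From day 21 to day 60 (0 with edgeR, 847 at an unadjusted p under 0.05) they were 114, 12, 21, 244 and 19, and 5 with the 4 libraries alone.

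With each library left out in turn a group is left with 1 library, the fit pools the spread and that library is assumed to vary like the other groups. The counts then ran from 1954 to 5037 at day 1, 2941 to 5315 at day 3, 4476 to 6949 at day 7, 2628 to 5593 at day 21 and 2654 to 5317 at day 60. Between neighbouring times they ran from 239 to 557, from 0 to 1412, from 2 to 228 and from 0 to 2, and for all groups from 4377 to 6881. Genes reversing between times ran from 39 to 160 in these fits, and were 270 with the replicate block. That block also moved the genes highest at day 1 from 917 to 1532 and at day 3 from 667 to 1001, and the overlap of day 1 with day 21 from 3085 to 4699 and with day 60 from 3034 to 4585. The cause was not tested.

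The camera calls of lists depend on the correlation assumed between genes. With an estimated correlation the number of lists called went from 22 to 5 at day 1, 24 to 4 at day 3, 25 to 0 at day 7, 22 to 3 at day 21 and 22 to 6 at day 60, and from 14 to 0, 19 to 1, 22 to 0 and 9 to 0 between neighbouring times. Under the 5 other alternatives the number at day 7 ran from 25 to 29. By fry it was 7 from day 7 to day 21 and 0 from day 21 to day 60. Fry was not run with libraries left out, and by camera with all libraries these numbers were 22 and 9. With libraries left out the last of these ran from 5 (without day 60 replicate 2) to 11. The 315 list tests include many that had no call to lose. Over all of them, 160 lost their call with an estimated correlation, 45 lost and 16 gained it with fry, and 3 lost and 14 gained it with the replicate block. With DESeq2 size factors 1 lost it, and without a filter or with TMM factors free of other-cell and matrix genes 0 did.

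Among results of named genes, 5 calls were lost and 1 gained with DESeq2 size factors, 25 and 23 with limma-voom, and 1 and 71 with the replicate block, while the DESeq2 test gained 60. With libraries left out 1340 were lost, 58 gained and 2 passed with the opposite sign. No gene called with all libraries passed with the opposite sign in these fits. The 2 results were those of Timp1, which had 1.31 CPM in sham replicate 1 and 227.9 in sham replicate 2. With libraries left out its log2 fold change ran from -1.05 to 6.38 at day 7 (-0.06 with all libraries) and from -1.25 to 6.18 at day 60 (-0.26), with the highest values without sham replicate 2. Calls of landmark genes numbered 62 of 125 and stayed within 1.5 times under every alternative run for them (51 to 84). Low depth limits what replicate 1 shows, where 3 counts are the floor, yet thinning replicate 2 to that depth left 4801 genes changed at day 1 against 4774.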

Other observations

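The genes of this paragraph were chosen after their values were seen, except for Cxcl13, and no list of B cell genes was tested. Cxcl13, which draws B cells, had 10.7 ± 0.791 CPM at day 7, 326 ± 45.5 at day 21 and 875 ± 209.8 at day 60. Igj, the joining chain of antibodies, was at 30.7 and 20.2 CPM in the day 60 libraries against 0.813 CPM on average in sham (log2 fold change 4.93 ± 0.96, edgeR adjusted p = 0.00456, higher in both libraries). At day 1 (log2 fold change -3.49) and day 7 (-2.96) Igj was called lower than sham. Pou2af1, a coactivator of antibody genes, was at 0.457 CPM in sham, 6.15 at day 3, 34.8 at day 21 and 46.1 at day 60 (at day 60 log2 fold change 6.97 ± 1.20, edgeR adjusted p = 0.0025). The B cell receptor gene Cd79a had 2.18 and 3.73 CPM at day 60 and 0.398 on average in sham, and did not pass (log2 fold change 2.84 ± 1.47, edgeR adjusted p = 0.167). The effect of leaving out a library was not run for Igj, Pou2af1 and Cd79a.

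Il11, a cytokine gene, was abundant at day 1 alone among the 6 groups. It had 0.836 and 0.0577 CPM in sham, 1004.7 and 742.6 at day 1 and 14.2 and 2.27 at day 3, and at most 1.27 CPM in any later library.

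A set of genes differed between replicates in every group. Of 13792 genes with a mean of at least 1 CPM, 87 were at least 8-fold higher in replicate 2 in all 6 groups, with 0.5 CPM added to both, and 1 was higher in replicate 1. C4b is the one among them that the naming rule names, and C4a, Gapdh and Eno1 are others, picked here after their values were seen. C4b counts in the complement list, and Gapdh and Eno1 in the glycolysis list. Whether both replicates were counted with the same settings, above all for reads that match several genes, is not stated, so the levels of these genes and the shares of these lists are uncertain.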
